A study of Caenorhabditis elegans with 10 samples.

How the data were processed

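The series measured RNA of *Caenorhabditis elegans* larvae at the L2/L3 stages, grown at 25 °C, on Affymetrix *C. elegans* tiling arrays, with 1 array per sample and 10 arrays in all. In 6 samples the RNA came from the PVD and OLL sensory neurons by mRNA tagging. In that method an epitope-tagged poly(A) binding protein is expressed from a cell-specific promoter, here a fragment of *ser-2*, and the messages bound to it are recovered by immunoprecipitation from whole-animal lysate. In the other 4 samples total RNA was taken from whole-animal lysate with no immunoprecipitation. Per the labels' protocols, every sample was amplified and biotin-labelled with the same NuGEN kits.

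The deposited table holds 1 log2 value per gene identifier and array, for 18451 identifiers, with 0 missing values. The authors made these log2 values with RMA (background correction, normalization between arrays and summary of probes), per the submitters' processing notes, which name no version. That the scale is log2 was read from the values, whose range on each array is that of RMA output on the log2 scale. The gene models, the genome build, the assignment of probes to genes and any filter are not given in the sources used here. No detection calls or background levels were used here, so a low value is not known to be above background, and folds that end in the dim range depend on how RMA handled background. Array medians lay between 6.51 and 6.77, so the columns were not identical in distribution. The number of arrays, not a count, limits the precision of every value. All 10 columns carried the identifier of a sample, and 0 further columns were present. No pair of arrays of a group held the same values: the highest correlation between 2 arrays was 0.984. Any 2 arrays of 1 kind of sample, PVD/OLL or whole animal, held an identical value for 1 to 9 genes. A PVD/OLL array and a whole-animal array did so for 0 genes in every pair, also in the pair with the highest correlation, 0.94. The wild-type and *mec-3* whole-animal arrays that correlated least, at 0.894, held an identical value for 7 genes. These values argue against 1 joint normalization of the 2 kinds, though how they were normalized was not checked here.

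Rows are named only by WormBase gene identifiers. The table of gene names used here (WBcel235 annotation, 46926 rows) holds 0 of the 18451 identifiers. The files used here do not pair the identifiers with names, so no symbol, position or function was assigned to any row, and *mec-3* itself was not analysed here. The 45 lists of gene functions and cell types that had been fixed before the data were examined were not tested for the same reason, nor were the planned set tests on them with their alternatives.

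Groups were taken from the sample titles, which number the samples as biological replicates. The comparisons and the fits were fixed before the data were examined. *mec-3* mutants were compared with wild type in PVD/OLL with the 6 PVD/OLL arrays alone, and in whole animals with the 4 whole-animal arrays alone. PVD/OLL was compared with whole animals within each genotype in 1 fit of all 10 arrays with a mean per group. The same fit gave the difference of differences, the *mec-3* difference in PVD/OLL minus that in whole animals, and the enrichment averaged over both genotypes. Each fit used lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited values, without a filter, with two-sided tests and Benjamini-Hochberg adjustment over all 18451 rows. A gene is called different where the adjusted p lies under 0.05. Differences are in log2 units with the moderated standard error (SE). The rule for genes named in the text, fixed before the data were examined, took *mec-3*, then for each comparison the 10 genes with the largest difference in each direction among called genes whose groups did not overlap, then members of the gene lists. Because identifiers are not paired with names here, only the first 2 in each direction are given, for the *mec-3* comparison in PVD/OLL and for the wild-type enrichment, and the same genes are followed in the other comparisons. The single gene called for the difference of differences is given as well.

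Replicate numbers are shared between groups. The numbers were not taken as pairs, and the fit with a replicate block is given only as an alternative. Other alternatives were quantile normalization across the arrays, centring of each array on its median, removal of the dimmest 50% or 25% of genes, an intensity trend with a robust prior, array weights, another set of arrays in the fit, a minimum of 1.5-fold, an adjusted p under 0.10, and each array left out in turn.

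The fits were tested on simulated data, with the spread of the real genes and groups and 200 of 18451 genes changed. For the *mec-3* comparison in PVD/OLL, 17.9% of 2-fold, 83.6% of 4-fold and 95.5% of 8-fold changes were recovered. For the comparison in whole animals 0% of 2-fold, 0% of 4-fold and 59.1% of 8-fold changes were recovered. For the difference of differences the shares were 0%, 44.8% and 81.8%. For the enrichment they were 29.9%, 83.6% and 95.5% in wild type and 31.3%, 71.6% and 98.5% in *mec-3*. Unchanged genes called by mistake numbered 2 for *mec-3* in PVD/OLL, 0 for *mec-3* in whole animals, 8 for the difference of differences, where the real data gave 1 call, 23 for the wild-type enrichment and 3 for the *mec-3* enrichment. The shares recovered and the mistaken calls hold for data with 200 changed genes, since the cutoff set by the adjustment depends on how many genes change. The 8 mistaken calls are thus no reference for the 1 real call. In the real whole-animal comparison 21.5% of genes had an unadjusted limma p under 0.05. There 1023 genes were called, with a median difference of 1.99 (log2, without sign). The shares are therefore not the power of the real comparisons. The *mec-3* comparison and the enrichment share arrays. Their overlap was therefore set beside 100 simulations of unchanged groups on those arrays.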

Results

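RNA was profiled from 2 kinds of sample in wild-type (N2) and *mec-3(e1338)* mutant larvae: PVD/OLL neurons recovered by mRNA tagging, with 3 arrays per genotype, and whole animals, with 2 arrays per genotype. PVD is a nociceptive neuron with a highly branched dendrite along the body wall, and OLL is a pair of sensory neurons of the head. *mec-3* encodes a LIM homeodomain transcription factor required for the fate of touch neurons and for the branching of the PVD dendrite. The series was designed to find genes that *mec-3* regulates in PVD. Whole animals served as the reference. The level of *mec-3* itself was not analysed here, since the gene identifiers were not paired with names, so it gives no check of the genotypes.

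The first principal component held 42.8% of the variance and parted PVD/OLL arrays, at -59.7 to -6.18, from whole-animal arrays, at 22.9 to 100.2. The second held 28% and parted the genotypes in both kinds of sample, with wild-type arrays at 17.95 to 50.7 and *mec-3* arrays at -71.0 to -13.2. Arrays of *mec-3* PVD/OLL correlated with each other at 0.982 to 0.984 and arrays of wild-type PVD/OLL at 0.961 to 0.977, where replicate 3 was the farthest from the others. The whole-animal pairs correlated at 0.974 in *mec-3* and 0.952 in wild type. Arrays of *mec-3* PVD/OLL correlated more highly with whole animals of their own genotype, at 0.928 to 0.940, than with wild-type whole animals, at 0.847 to 0.891. Wild-type PVD/OLL arrays did not part that way: they correlated at 0.912 to 0.929 with wild-type whole-animal replicate 1, at 0.887 to 0.899 with replicate 2, and at 0.890 to 0.904 with *mec-3* whole animals.

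**Figure D1:**
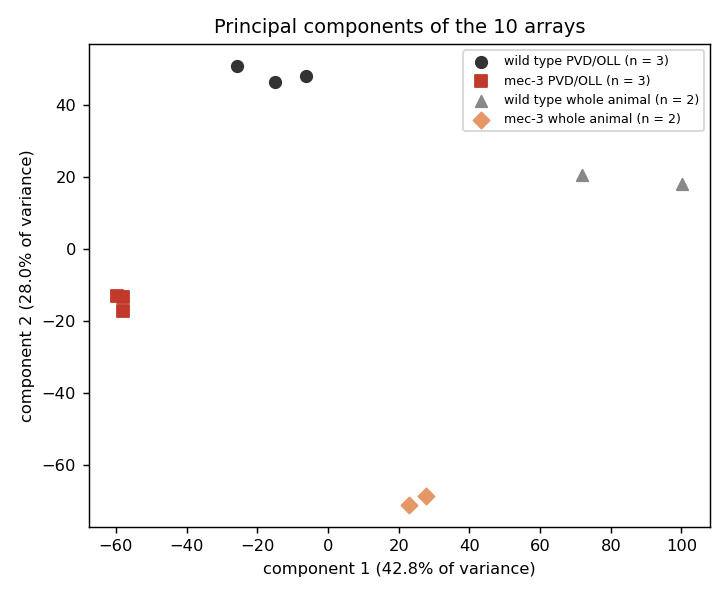
Scores of the 10 arrays on the first (x axis, 42.8% of variance) and second (y axis, 28%) principal component of the log2 values of 18451 genes, with 1 point per array and a symbol per group. The first component parts PVD/OLL from whole animals, and on the second all wild-type arrays lie above 0 and all *mec-3* arrays below 0.

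The comparison of *mec-3* with wild type in PVD/OLL asks which transcripts recovered from PVD/OLL by mRNA tagging differ between the genotypes. In *mec-3* PVD/OLL, 655 genes were lower and 476 were higher than in wild type, out of 18451 tested (limma, adjusted p under 0.05). The lower genes included the large differences: 217 fell by at least 4-fold and 50 by at least 16-fold, whereas 25 rose by at least 4-fold and 1 by at least 16-fold. The median difference was -1.55 (log2) among lower genes and 1.08 among higher genes. Of the lower genes, 368 lay in the top 25% of wild-type PVD/OLL values, and 10 of these dropped into the bottom 25% in *mec-3*. All 1131 called genes had groups that did not overlap, as did 27.4% of all genes, where chance gives 10%.

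The gene with the largest fall was WBGene00086560. It measured 14.20 ± 0.17 (log2, SD, n = 3) in wild-type and 5.42 ± 0.89 (n = 3) in *mec-3* PVD/OLL, a 442-fold drop (log2 difference -8.79, SE 0.40, limma adjusted p = 1.59e-05). WBGene00001728 dropped 189-fold, from 13.02 ± 0.16 to 5.45 ± 0.87 (log2 difference -7.57, SE 0.39, limma adjusted p = 2.76e-05). The largest rise was that of WBGene00013007, from 6.16 ± 0.53 to 10.44 ± 0.08, which is 19.4-fold (log2 difference 4.28, SE 0.27, limma adjusted p = 7.79e-05). WBGene00008565 rose 12.2-fold, from 7.26 ± 0.92 to 10.87 ± 0.32 (log2 difference 3.61, SE 0.42, limma adjusted p = 0.00223). These 4 differences stayed past the threshold in PVD/OLL with each PVD/OLL array left out.

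The count of 1131 fell with each PVD/OLL array left out. It was 1036, 721 and 959 without wild-type replicates 1, 2 and 3. Without *mec-3* replicates 1, 2 and 3 it was 494, 504 and 452. Each of these fits also had fewer arrays, so a fall does not by itself mark an array as deviating. The count was 1806 with array weights. Centring each array on its median gave 709 higher and 583 lower genes, with the median over all genes at 0.03 (log2) in place of -0.07, so which direction held more genes depended on the scaling. Quantile normalization gave 571 higher and 624 lower genes.

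In whole animals, 531 genes were lower and 492 were higher in *mec-3* than in wild type (limma, 4 arrays, adjusted p under 0.05). The falls were again larger than the rises, with 346 genes lower and 161 higher by at least 4-fold, and 89 lower and 2 higher by at least 16-fold. The genes named above differed in the same direction there. WBGene00086560 dropped from 14.87 ± 0.02 (log2, SD, n = 2) to 7.98 ± 1.49 (n = 2), a difference of -6.90 (limma adjusted p = 0.00463; -7.95 and -5.84 without *mec-3* replicates 1 and 2), and WBGene00001728 dropped 141-fold, from 12.95 ± 0.08 to 5.81 ± 0.12 (limma adjusted p = 0.00057). WBGene00013007 rose 26.4-fold (limma adjusted p = 0.00171) and WBGene00008565 8.12-fold (limma adjusted p = 0.0160). The call of WBGene00008565 was lost without either *mec-3* whole-animal array (limma adjusted p = 0.0989 without replicate 1 and 0.0611 without replicate 2).

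With 2 arrays per genotype the whole-animal count was unstable: it was 160 and 153 without *mec-3* replicates 1 and 2, 1591 without wild-type replicate 1, and 2481 when all 10 arrays shared 1 estimate of the spread. Without an array, the lone array of its group was assumed to vary like the other group. The direction with more genes changed with the setting: in place of 492 higher and 531 lower genes, quantile normalization gave 271 and 447, centring on the median 607 and 532, the fit of all 10 arrays 1433 and 1048, and leaving out the dimmest 50% of genes 994 and 597. Without *mec-3* replicates 1 and 2 the splits were 19 to 141 and 13 to 140.

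The genotype differences of PVD/OLL and of whole animals, measured on separate arrays, mostly had the same direction. Of the 1131 genes that differed in PVD/OLL, 1093 (96.6%) lay on the same side of 0 in whole animals: 628 of the 655 lower genes and 465 of the 476 higher ones. Of the genes not called in PVD/OLL, 66.8% did. Both comparisons called 338 genes lower and 182 higher, where independent lists would share 18.9 and 12.7, and 0 genes were called in opposite directions. Of the 242 genes that differed at least 4-fold in PVD/OLL, 241 went the same way in whole animals and 194 did so by at least 4-fold. Genes called lower in *mec-3* PVD/OLL had a median of -1.70 in whole animals against -1.55 in PVD/OLL, and those called higher 1.37 against 1.08. Among the genes called in whole animals, the slope of the PVD/OLL on the whole-animal difference was 0.638. All 10 genes that dropped from the top to the bottom 25% in PVD/OLL were also called lower in whole animals.

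Across all 18451 genes the 2 differences correlated at r = 0.71 (Spearman 0.55); genes are not independent replicates. The count of 520 genes called alike in both was 133 and 134 without *mec-3* whole-animal replicates 1 and 2, and 323, 312 and 296 without *mec-3* PVD/OLL replicates 1, 2 and 3. The share with the same direction stayed at 92.4% to 99.0% with each array left out.

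**Figure D2:**
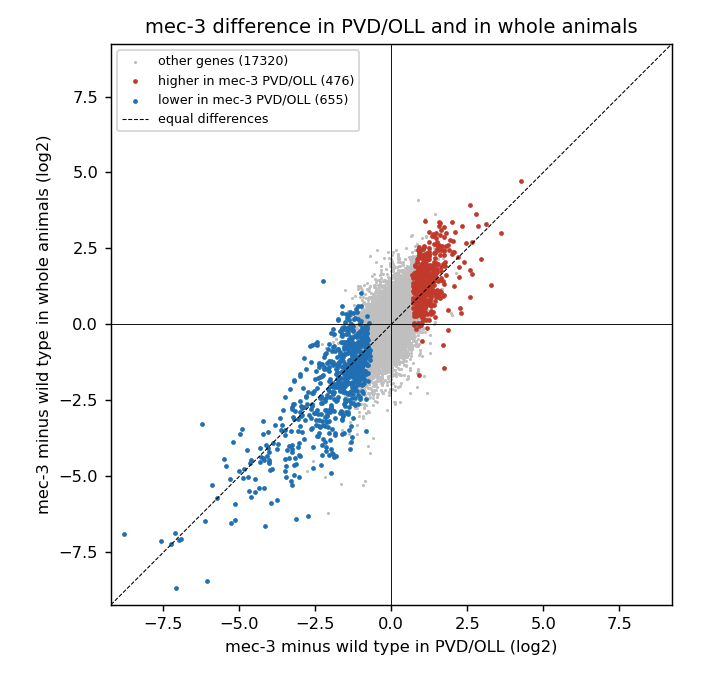
Difference between *mec-3* and wild type of each of 18451 genes in PVD/OLL (x axis, log2) and in whole animals (y axis, log2), 1 point per gene, with the dashed line at equal differences. The 655 genes lower (blue) and 476 higher (red) in *mec-3* PVD/OLL lie almost all on the same side of 0 in whole animals, 1093 of 1131.

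Whether the *mec-3* difference was different in PVD/OLL than in whole animals was tested as a difference of differences over all 10 arrays. A single gene passed (limma, adjusted p under 0.05), and 1809 genes (9.80%) had an unadjusted p under 0.05. The gene, WBGene00016234, was 13.3-fold lower in *mec-3* than in wild-type whole animals (9.35 ± 0.24 against 13.08 ± 0.12, SD, n = 2 each). In PVD/OLL it was 11.06 ± 0.11 in *mec-3* and 11.66 ± 0.24 in wild type (n = 3 each), which did not pass (limma adjusted p = 0.115). The difference of differences was 3.13 (log2, SE 0.32, limma adjusted p = 0.0157). It stood at 2.96 to 3.29 with each array left out, but the call was lost without any one of 8 of the 10 arrays, and adjusted p was then 0.0624 to 0.170. Over all settings tried its limma adjusted p ranged from 0.00318 to 0.170. The test found no gene without wild-type PVD/OLL replicates 1 or 3, any *mec-3* array or wild-type whole-animal replicate 2, and called 5 genes without wild-type PVD/OLL replicate 2 and 16 without wild-type whole-animal replicate 1.

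Of the 1131 genes called in PVD/OLL, 0 passed the difference of differences in limma and 304 had an unadjusted p under 0.05. Adjusted over these 1131 genes alone, 52 passed, but the genes were chosen on PVD/OLL arrays that also enter this test, which is not independent evidence. In 107 of these 304 the PVD/OLL difference went further in its direction than the whole-animal one (78 lower and 29 higher genes). In the other 197 it was the smaller (118 lower and 79 higher genes). A further view is the 87 called genes, 60 lower and 27 higher, whose whole-animal value did not move in the same direction by at least 0.32 (log2). Their median difference in PVD/OLL was 1.14 (log2, without sign) and their largest 2.26. Of these, 66 had an unadjusted p under 0.05 for the difference of differences, and the lowest limma adjusted p was 0.136. Since the 87 genes were chosen for differing in PVD/OLL and not moving in whole animals, the 66 follow in part from the choice and are not independent evidence. In simulated data of this design, 0% of 2-fold and 44.8% of 4-fold differences of differences were recovered.

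**Figure D3:**
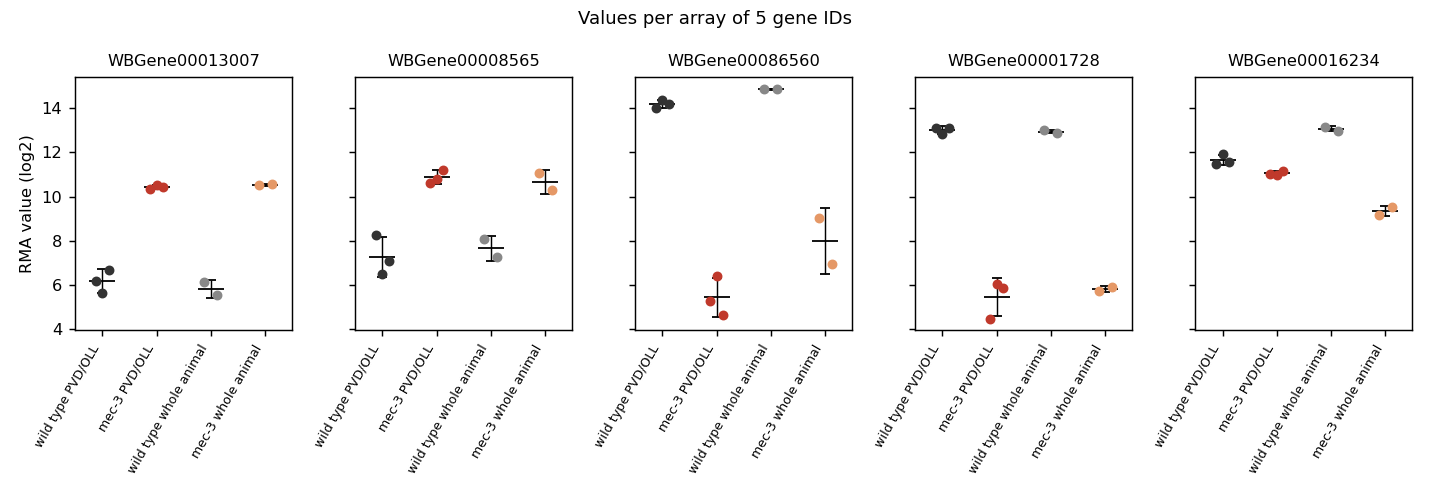
RMA values (y axis, log2) of 5 gene identifiers on each array (points), by group (x axis), with the group mean (bar) and SD (whiskers). WBGene00013007 and WBGene00008565 are higher, and WBGene00086560 and WBGene00001728 lower, in *mec-3* than in wild type both in PVD/OLL (n = 3 per group) and in whole animals (n = 2), while WBGene00016234 is 13.3-fold lower in *mec-3* whole animals and its difference in PVD/OLL is -0.61 (log2).

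The comparison of PVD/OLL with whole animals asks which transcripts the tagged neurons are enriched for. In wild type 1773 genes were higher and 3496 lower in PVD/OLL (limma, 10 arrays, adjusted p under 0.05), and in *mec-3* 1400 were higher and 3521 lower. The immunoprecipitation was done only on the PVD/OLL samples, and the 2 kinds of sample may have been normalized in separate runs. Cell type, preparation and processing therefore cannot be told apart in these counts. The enrichments of the 2 genotypes, as differences that share no arrays, correlated across genes at r = 0.71 (Spearman 0.71). Both genotypes called 879 genes enriched and 1987 depleted, against 134.5 and 667.1 for independent lists, and 16 genes in opposite directions. The calls of both genotypes used the same estimate of the spread of each gene, from all 10 arrays. That by itself pairs calls, so independent lists are a low reference for these counts. Of the 1773 genes enriched in wild type, 1605 (90.5%) lay above whole animals in *mec-3* as well.

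Most enrichments were small. The median of the 879 genes was 1.11 (log2) in wild type and 1.08 in *mec-3*, and 18 of them were enriched at least 4-fold in both genotypes. With all arrays, a single gene was enriched at least 16-fold in both, WBGene00011141, at 11.02 ± 0.12 (SD, n = 3) in wild-type PVD/OLL and 5.08 ± 0.52 (n = 2) in whole animals. Its enrichment was 61.2-fold in wild type (limma adjusted p = 0.000278) and 27.1-fold in *mec-3* (limma adjusted p = 0.000639). The *mec-3* value depended on single arrays: as log2 it was 4.76, and 3.90, under 16-fold, without whole-animal replicate 1 and 5.62 without replicate 2. Its levels in *mec-3* and wild-type PVD/OLL were 11.21 ± 0.19 and 11.02 ± 0.12 (limma adjusted p = 0.606). WBGene00002113 was enriched 13.7-fold in wild type and 5.17-fold in *mec-3* (limma adjusted p = 0.000286 and 0.00142). The largest falls in wild type were those of WBGene00007713, 25.5-fold from 9.01 ± 1.99 in whole animals (log2, SD, n = 2) to 4.34 ± 0.50 in PVD/OLL, and WBGene00016164, 24.6-fold (limma adjusted p = 0.00208 and 0.00115). The log2 difference of WBGene00007713, -4.67, was -6.07 and -3.27 without wild-type whole-animal replicates 1 and 2, and that of WBGene00016164, -4.62, was -3.92 without wild-type PVD/OLL replicate 3. In *mec-3* WBGene00016164 was 6.48-fold lower (limma adjusted p = 0.0125, and 0.106 without *mec-3* whole-animal replicate 1), and the difference of WBGene00007713, -1.81 (log2), did not pass (limma adjusted p = 0.0896). It passed with array weights and with only the *mec-3* arrays in the fit (limma adjusted p = 0.040 and 0.0383), and was -0.93 and -2.69 without *mec-3* whole-animal replicates 1 and 2 (limma adjusted p = 0.503 and 0.0740). The enrichments of WBGene00007713 were not shown to differ between genotypes (difference of differences 2.86, limma adjusted p = 0.400).

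The excess of depleted genes varied with the level of the genes and with the scaling. Among the dimmest 20% of genes 917 were lower and 11 higher in wild-type PVD/OLL, and 873 lower and 4 higher in *mec-3*, with medians of -0.48 and -0.52 (log2). Among the brightest 20% wild type had 649 higher and 606 lower genes, while *mec-3* had 440 higher and 832 lower, with a median of -0.15, so in *mec-3* the excess was not confined to dim genes. The median over all genes was -0.21 in wild type and -0.28 in *mec-3*, and became 0.03 and 0.02 after quantile normalization. The split then was 2439 higher to 2216 lower genes in wild type and 1900 to 1702 in *mec-3*. After centring on the median it was 2093 to 2919 and 1746 to 2671, and with the dimmest 50% left out 1658 to 1396 and 1305 to 1737. Without wild-type whole-animal replicate 2, 2304 genes were called in wild type in place of 5269, and with the 5 wild-type arrays alone 2451. In *mec-3* the count of 4921 fell to 2939, 3166 and 2808 without PVD/OLL replicates 1, 2 and 3, and to 1969 and 1926 without whole-animal replicates 1 and 2. The 879 genes enriched in both became 503 without wild-type whole-animal replicate 2, 403 and 388 without *mec-3* whole-animal replicates 1 and 2, and 522 and 508 without *mec-3* PVD/OLL replicates 1 and 3.

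**Figure D4:**
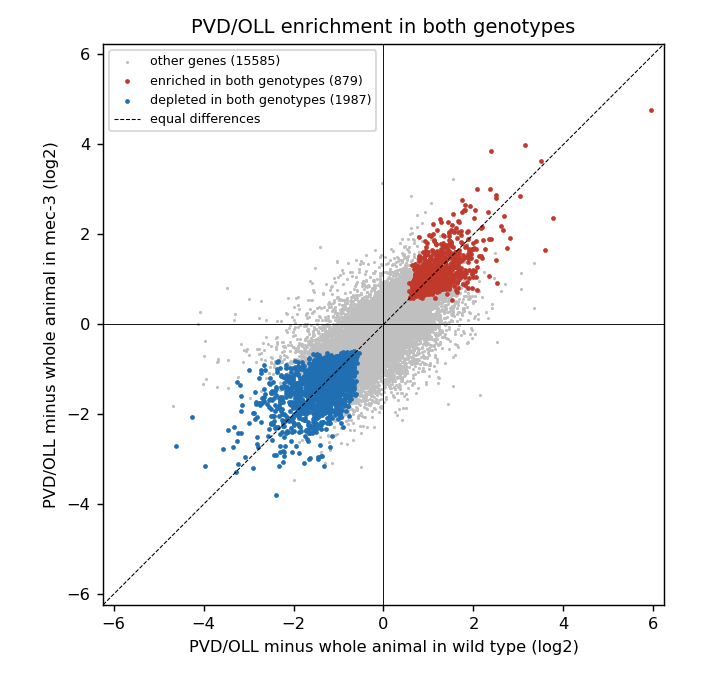
Difference between PVD/OLL and whole animals of each of 18451 genes in wild type (x axis, log2) and in *mec-3* (y axis, log2), 1 point per gene, with the dashed line at equal differences. The 879 genes enriched (red) and 1987 depleted (blue) in both genotypes lie along the line, and WBGene00011141 stands at the upper right.

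The genes lower in *mec-3* PVD/OLL were set against those enriched in these neurons. Of the 655 lower genes 53 were enriched in wild-type PVD/OLL, where independent lists would share 62.9, and 233 were depleted, where they would share 124. Against the enrichment measured in *mec-3* the counts were 28 and 178, where independent lists would share 49.7 and 125. Simulated unchanged groups on the shared arrays gave 0 shared genes in each of 100 draws, but with no effect the adjustment leaves few genes to share, so this is no reference for the counts of 53 and 28. The 3 wild-type PVD/OLL arrays enter both lists and are too few to be split, and sharing them by itself pairs low values in *mec-3* with enrichment: the covariance of the 2 differences was 0.047 against -0.058 in the simulations, a difference of 0.105. The *mec-3* enrichment shares the *mec-3* PVD/OLL arrays instead, which by itself pairs low values in *mec-3* with depletion. For it the covariance was 0.058 against 0.03 in the simulations, so 28 against 49.7 is not free of that sharing. With no array left out, the count of 53 became 73 against 120 with the dimmest 50% of genes left out. After quantile normalization it was 67 against 82.5. Among these settings it lay over that of independent lists only with array weights, 68 against 67.7. Whether the count of 53 lay under or over that of independent lists depended on single arrays. It was 81 against 51.1 without wild-type PVD/OLL replicate 1, 39 against 29.9 without replicate 2, and 37 against 29.1 without wild-type whole-animal replicate 2. It was 22, 22 and 24 against 29.6, 29.5 and 27.6 without *mec-3* PVD/OLL replicates 1, 2 and 3.

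By the enrichment averaged over both genotypes, 809 genes were enriched and 2311 depleted at least 2-fold. Of the enriched genes 46 (5.69%) differed between genotypes in PVD/OLL, 27 lower and 19 higher in *mec-3*. Of the depleted genes 233 (10.1%) differed, 178 lower and 55 higher, and of the remaining 15331 genes 852 (5.56%) differed, 450 lower and 402 higher. In each class most of these lay on the same side of 0 in whole animals, whether or not they passed there: 40 of 46 enriched, 227 of 233 depleted and 826 of 852 other genes.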

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

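The tests in this part, other than the difference of differences and the ratio of slopes for carried-over RNA, were chosen after the result was seen. The groups of 2 and 3 arrays were too small for a search for single deviating arrays.

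WBGene00016234 stood out because its *mec-3* difference was not the same in PVD/OLL and in whole animals: -0.61 against -3.73 (log2), a difference of 3.13 with limma adjusted p = 0.0157. It was the only gene of 18451 to pass that test, and the call was lost without any one of 8 of the 10 arrays (adjusted p 0.0624 to 0.170).

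The genotype differences of PVD/OLL reappeared in whole animals, with 96.6% of the 1131 called genes on the same side of 0 and single genes that differed more than 100-fold in both. Of the 1195 genes called after quantile normalization (1046 of them among the 1131), 96.4% went the same way. That cannot decide on the normalization. It moved the median over all genes in PVD/OLL only from -0.067 to 0.034 (log2), while called genes had a median difference of 1.29 (without sign). With any one wild-type array left out, at least 92.4% of the called genes went the same way. No conclusion on a single deviating array follows, since no array enters both comparisons and could hardly make them agree. If both kinds of sample lie on 1 scale, which is not known, the tables argue against whole-animal RNA carried over alike for all transcripts. This holds for it as the source of the shared genes at 50% or more of their whole-animal level. Such carry-over would keep every abundant transcript near the level of those genes. Of the 3730 genes bright in whole animals of both genotypes, 30 were at least 4-fold lower in PVD/OLL in both, 21 of them without a genotype call. The 30 became 23 after quantile normalization, 26 after centring on the median, and 26 to 32 with each PVD/OLL array left out. Of the 520 shared genes, in the genotype where they were higher, 58.5% lay at 50% or more of their whole-animal level. That share was lower without either *mec-3* whole-animal array. Carry-over of only some transcripts, or as the source of shared genes at lower levels, stays open: among genes that differed in whole animals, the slope of the PVD/OLL on the whole-animal difference was 0.54 in 44 genes enriched at least 2-fold and 0.666 in 464 depleted genes, a ratio of 0.811, which lay at 1.44 and 1.52, on only 4 and 3 enriched genes, without *mec-3* whole-animal replicates 1 and 2 and between 0.698 and 0.866 with any other array left out. A culture, stage or array batch that parts the genotypes cannot be told apart from the mutation, since no label gives a batch and both predict the correlation of 0.71 across genes, and a body-wide effect of the genotype, or of other differences between the strains, also remains open and untested.

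The 1131 genes called between genotypes in PVD/OLL come from 3 against 3 arrays. Of the 10 splits of those arrays, 1, the real one, called that many, and the highest other split called 0. So few splits cannot give a share under 0.05.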

How the results depend on the processing

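No direction of a named gene was reversed in any alternative, and 221 of their 236 alternative values kept their side of the threshold, while 13 lost it (10 of them for WBGene00016234) and 2 gained it. Without the sets that leave out single arrays, counts moved by more than 1.5 times as follows; the cause was not tested, except that fewer genes tested or a looser threshold act by construction. In PVD/OLL, the *mec-3* comparison (1131) gave 1806 with array weights and 1892 at an adjusted p under 0.10. In whole animals (1023) it gave 1591 with the dimmest 50% left out, 2481 with all 10 arrays in the fit and 1986 at an adjusted p under 0.10. The wild-type enrichment (5269) gave 3054 with the dimmest 50% left out and 2451 with only its own groups in the fit, and 3045 without both wild-type PVD/OLL replicate 3 and whole-animal replicate 2, an alternative chosen after seeing the data. The *mec-3* enrichment (4921) gave 3042 with the dimmest 50% left out. The difference of differences (1) gave 2 after quantile normalization, 2 with an intensity trend, 8 with the dimmest 50% left out, 5 at an adjusted p under 0.10, and 0 without those 2 wild-type arrays. The 520 genes alike in both sample types became 806 with the dimmest 50% left out, and the 53 lower and enriched genes 28 with the *mec-3* enrichment.

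With the replicate block, the *mec-3* comparison in PVD/OLL called 843 genes in place of 1131, with 786 shared; the difference of differences called 0 (WBGene00016234, adjusted p = 0.106) and the lower and enriched genes were 35. The numbers were not shown to mark pairs. As deviations from their group means, same-numbered PVD/OLL arrays of the 2 genotypes correlated at -0.058, 0.031 and 0.038, and not each array best with its own number. Between wild-type PVD/OLL and wild-type whole animals the deviations correlated at 0.19 for replicate 1 and -0.028 for replicate 2. For PVD/OLL replicate 3 with whole-animal replicate 2 the value was 0.18. The other counts stayed within 1.5 times under the block.

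With single arrays left out, the counts ranged from 452 to 1036 (*mec-3* in PVD/OLL), 153 to 1591 (*mec-3* in whole animals), 2304 to 5643 (wild-type enrichment), 1926 to 3166 (*mec-3* enrichment), 0 to 16 (difference of differences), 22 to 81 (lower and enriched), 133 to 548 (alike in both sample types) and 388 to 957 (enriched in both genotypes). Each of these fits also had fewer arrays, so a lower count does not by itself mark an array as deviating. The planned tests of gene lists and their alternatives were not run, because the identifiers were not paired with names here. No background level was used, so how far dim genes were measured is not known.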

Other observations

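The 520 genes that differed alike in PVD/OLL and whole animals were seldom PVD/OLL-enriched. By the enrichment averaged over both genotypes, 46 of them (8.85%) were enriched and 263 (50.6%) depleted, against 14.4% and 32.8% of all genes. The genes were chosen on the same arrays that give this enrichment. The shares of all genes were not matched on level and hold for the deposited scaling only. The median difference between PVD/OLL and whole animals of the 338 lower genes was -0.93 (log2) in wild type and -0.47 in *mec-3*, and that of the 182 higher genes 0.19 and -0.63, against -0.21 and -0.28 over all genes. Among genes called in PVD/OLL the slope of the whole-animal on the PVD/OLL difference was 1.06, and that of the PVD/OLL on the whole-animal difference among genes called in whole animals was 0.638. Neither slope was corrected for the selection of genes or for error in the values.

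The test of dim genes was chosen after the result was seen, as was the count of enriched genes with an unadjusted p under 0.05, and the test of unequal spread before. More genes were lower than higher in PVD/OLL than in whole animals, 66.4% of calls in wild type and 71.6% in *mec-3*. A candidate explanation is a lower background of dim genes on the PVD/OLL arrays. With the dimmest 50% left out the shares of lower calls were 45.7% and 57.1%, and after quantile normalization 47.6% and 47.3%. Without dim genes the excess thus ended in wild type and shrank in *mec-3*, where the brightest 20% of genes still had 832 lower and 440 higher calls, which leaves the explanation open for part of the pattern, and a real lack of those transcripts in the neurons was not tested.

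A hypothesis was that genes enriched in PVD/OLL are lower in the mutant relative to whole animals. Of the 809 genes enriched at least 2-fold by the genotype average, 57.8% had a negative difference of differences, with a median of -0.088 (log2) against -0.047 over all genes. That median lay at the 24.8th percentile of 10000 random lists matched on level. Simulations with no difference of differences, but with the unequal spread of the groups, gave 50.3% to 61.5% over 100 draws, so the share of negative values was no larger than the unequal spread may produce. At an unadjusted p under 0.05, 64 were negative and 36 positive, a share of 64% where simulations gave 53.8% to 78%, but both counts lay above the simulated ones, 29 to 60 and 11 to 30.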
